A study of Mus musculus with 7 samples.

How the data were processed

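Messenger RNA sequencing of mouse left ventricle was analysed from gene-level tables. The labels name 4 samples G3, described as telomerase-deficient, and 3 samples G3 PGC1aOE, described as the same kind of mouse with PGC1alpha overexpressed. All 7 samples carry the strain name C57BL/6J and an age of 12 months. Per the labels' protocols, hearts were snap frozen, RNA was taken with Trizol, and libraries were made with an Illumina TruSeq RNA kit, which does not mark strand. Samples were grouped by their genotype label. Nothing in the labels says whether libraries share an animal or a litter, so p-values measure the spread between these samples.

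The authors deposited 2 tables. The first holds read counts per Ensembl gene, as whole numbers that differ in their totals, with no normalization. The second holds FPKM, and the deposited FPKM equalled the deposited counts divided by the column total and by a single gene length per row, with a length range across samples of at most 0.00028 bp. It therefore added gene lengths and no further measurement. Per the submitters' processing notes, CASAVA and Bowtie 0.12.2 were used with the mm9 build. The program that counted reads, its annotation, its use of strand and its handling of reads that match several genes are not given in the sources used here. Genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes, Acot1 with its paralogs, and mitochondrially encoded genes with nuclear copies, are therefore uncertain, and reads from overlapping or antisense genes cannot be told apart.

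The count table lists 22027 genes. A table of gene names matched 21748 of these identifiers and left 279 unmatched, which held between 0.0231% and 0.0295% of counts per library. The reference in hand was of a later build than mm9, so no coordinates are printed. Its transcripts were used for GC content only, which was found for 99.8% of tested genes. Total counts ran from 10106705 to 16056740 per library.

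Counts were scaled by TMM and filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3, which kept 12674 genes and left out 9353. The main test was edgeR's quasi-likelihood F-test, 2-sided, robust, with group as the only term, and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are the libraries labelled G3 PGC1aOE minus G3. CPM values use TMM-scaled totals, and log2 CPM used a prior count of 2. Intervals are at 95% and come from the fitted standard error.

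Before the data were examined, 32 pathway lists and 17 marker lists of cell types and sample state were fixed. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01, adjusted over the 32 pathway lists and separately over the 15 marker lists that had enough members. The lung list and the sex-linked list were too small. Each list was tested again with a correlation estimated from the data and with fry, whose directional p asks whether the members move one way on balance. The genes of each list were also adjusted over the list alone. Single values between groups were compared with an exact permutation test over all 35 splits of the 7 libraries, 2-sided, whose smallest p is 0.0286.

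The rule for named genes was fixed in advance. Ppargc1a, Terc and Tert come first where listed. Up to 10 genes per direction by fold were to be named from those past the threshold with a mean log2 CPM of at least 2 and no overlap between groups. With fewer than 5, the 5 genes of smallest p in each direction are named instead and said not to pass. From each called pathway list, the 3 members of smallest p in the list's direction are named. From other described lists and from called marker lists, at most 2 members are named. Some genes that the rule selects are not reported here. Members outside the rule are marked as chosen after their values were seen.

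Alternatives fixed in advance were RLE and upper quartile scaling, other filters on low counts, DESeq2 1.42.0, limma voom with sample quality weights, limma on log2 FPKM with pseudocounts of 1 and 0.1, covariates for a text in the sample code and for Y-linked expression, removal of mitochondrially encoded genes, a replicate block, and each library left out in turn. Alternatives chosen after seeing the data removed each library's lowess trend on gene length or on GC content, or added a covariate for the number in the sample code, below 80 against 80 and above. Within-batch values are given as differences of list means or of log2 CPM. A batch here means a group by code number, and nothing in the labels says that it was a batch of animals or libraries. The first batch holds 3 libraries labelled G3 and 1 labelled G3 PGC1aOE, and the second holds 1 and 2.

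The scripts were tested on simulated counts for this comparison, drawn for the 12674 tested genes with 200 genes changed. The main test recovered 20.5% of genes changed 2-fold, 76.5% of those changed 3-fold, 89.5% at 4-fold and 99% at 8-fold. In a simulation of all 47 tested lists, a shift of 0.5 in the fibroblast list alone was called with an adjusted p of 0.0235 and 0 other lists. When the measured length trends were added, 4 other lists were called, and 0 after the trends were removed. Each gene was drawn independently, whereas the correlation estimated from the data reached 0.89, for cytosolic ribosomal proteins. The simulation therefore does not show how often lists of correlated genes are called without a group difference.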

Results

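The study sequenced RNA from the left ventricle of 12-month-old telomerase-deficient mice, a mouse line with shortened telomeres, with and without overexpression of PGC1alpha, a transcriptional coactivator of mitochondrial and fuel oxidation genes encoded by Ppargc1a. The question, as the series title puts it, concerned PGC1alpha levels and the heart. There were 4 libraries labelled G3 and 3 labelled G3 PGC1aOE. Total counts were 10106705, 12016705, 11218114 and 14119403 in G3 1 to 4, and 11576569, 14891420 and 16056740 in G3 PGC1aOE 1 to 3. The samples' descriptions also carry a code with a number, which is 40, 67, 50 and 83 for G3 1 to 4 and 55, 81 and 82 for G3 PGC1aOE 1 to 3. The code reads G2 in G3 1, G3 3 and G3 PGC1aOE 1 and G3 in the others. Before these it carries the letter C in G3 1 and G3 2, no letter in G3 3, the letter P in G3 4 and the letters PC in all 3 libraries labelled G3 PGC1aOE. The meaning of the code is not stated.

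Ppargc1a (ENSMUSG00000029167) was not higher in the libraries labelled G3 PGC1aOE. It stood at 89.1 ± 25.4 CPM (SD, n = 4) in G3 and at 68.3 ± 30.8 CPM (SD, n = 3) in those libraries, from 1038, 768, 1320 and 1153 counts against 1326, 603 and 789. The log2 fold change was −0.38 with an SE of 0.34 and a 95% interval from −1.12 to 0.36 (edgeR, adjusted p = 0.847), and the exact permutation p on log2 CPM was 0.314. The measured message therefore goes against the label, and every direction given for these libraries rests on the label alone. Without G3 PGC1aOE 1 the log2 fold change was −0.81, without G3 PGC1aOE 2 it was −0.15 and without G3 3 it was −0.23. Among libraries with code numbers below 80 the difference in log2 CPM was 0.26, and at 80 and above it was −0.78, beside −0.43 over all. Terc, the RNA component of telomerase, was not analysed here. Tert, its protein component, had too few counts to be tested.

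No single gene passed the threshold. The 5 genes of smallest p that were higher in the libraries labelled G3 PGC1aOE were Col3a1, Col14a1, Ptn, Igf2 and Cpxm1, and none of them passed. Col3a1 (ENSMUSG00000026043), a fibrillar collagen, measured 147 ± 13.2 CPM (SD, n = 3) against 60.6 ± 12.9 CPM (SD, n = 4), a log2 fold change of 1.28 with an SE of 0.24. Col14a1, a collagen found on fibril surfaces, differed by 0.95 with an SE of 0.23. The growth factor genes Ptn and Igf2 differed by 1.88 with an SE of 0.38 and by 1.59 with an SE of 0.34. Cpxm1, of the carboxypeptidase family, differed by 1.48 with an SE of 0.30. Igf2 averaged 58.8 ± 29.8 CPM (SD, n = 3) against 19.5 ± 4.63 CPM (SD, n = 4).

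On the lower side stood Acot1 (ENSMUSG00000072949), an acyl-CoA thioesterase, at 6.68 ± 1.88 CPM (SD, n = 3) against 16.9 ± 3.58 CPM (SD, n = 4), a log2 fold change of −1.34 with an SE of 0.27. Adra1a, the alpha-1A adrenergic receptor, differed by −1.40 with an SE of 0.34. Scn4a, a voltage-gated sodium channel, differed by −1.41 with an SE of 0.40, Galnt17, a glycosyltransferase gene, by −0.96 with an SE of 0.27, and Pcx, pyruvate carboxylase, by −0.65 with an SE of 0.19. All 10 of these genes had an adjusted p of 0.847. They did not overlap between the groups, which by itself fixes their sign within both code number batches. Such separation held for 581 of 12674 genes, or 4.58%, where chance gives 5.71%. edgeR called 0 genes, with 548 at an unadjusted p under 0.05, of which 387 were higher and 161 lower, against 633.7 expected by chance. DESeq2 called 3, Col3a1, Ptn and Acot1, and limma voom called 0. The biological coefficient of variation was 31.2%.

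**Figure D1:**
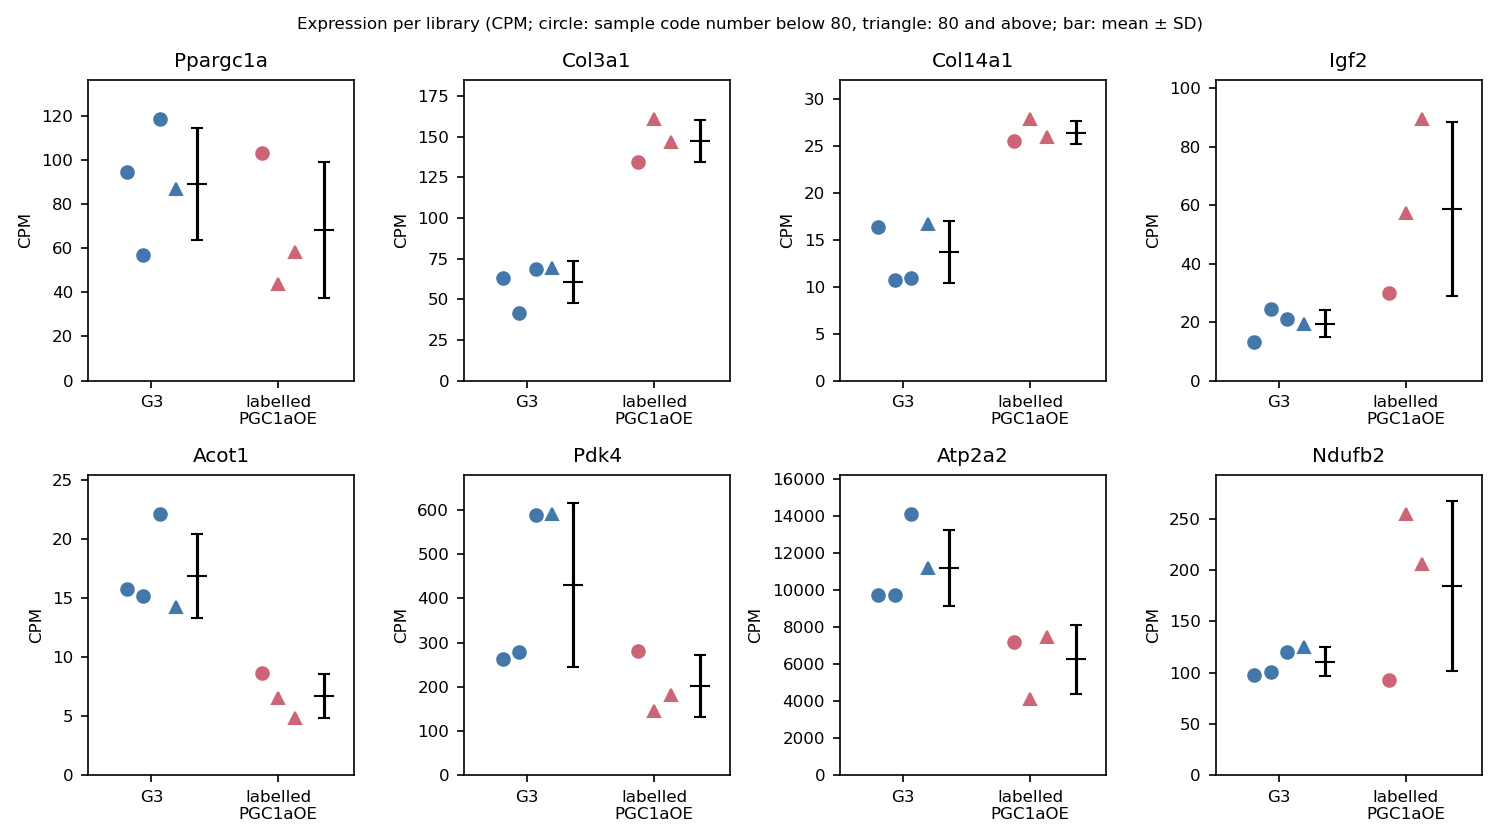
CPM of 8 named genes in each library, with libraries labelled G3 in blue and G3 PGC1aOE in red; the horizontal mark and bar beside each group are the mean and SD (n = 4 and n = 3), circles have a sample code number below 80 and triangles one of 80 or above. Ppargc1a overlapped between the groups, at 89.1 ± 25.4 CPM in G3 and 68.3 ± 30.8 CPM in the others, while Col3a1 stood at 60.6 ± 12.9 against 147 ± 13.2 CPM with no overlap.

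Fibroblast genes were higher together in the libraries labelled G3 PGC1aOE. Of the 14 fibroblast markers, 12 were higher, with a median log2 fold change of 0.75, and the mean of the list was 6.56 ± 0.22 log2 CPM (SD, n = 3) against 5.91 ± 0.14 (SD, n = 4). Pi16, a marker of adventitial fibroblasts, measured 98.9 ± 31.5 CPM (SD, n = 3) against 50.7 ± 8.69 CPM (SD, n = 4), and Col3a1 belongs to the list too. The list passed camera (adjusted p = 1.61e-07), and it was the only list of the 47 that also passed with an estimated correlation (adjusted p = 0.0395) and with fry (adjusted p = 0.0235). Both values were adjusted over the 15 marker lists alone, not over all 47. The unadjusted p was 0.0026 with the estimated correlation and 0.0016 with fry. No member passed when adjusted over all genes, and 6 passed when adjusted over the list alone. The exact permutation p of the list mean was 0.0286, the smallest that 35 splits can give. The difference in list mean was 0.38 below a code number of 80 and 0.88 at 80 and above, beside 0.65 over all. The list mean did not overlap between the groups, which by itself fixes its sign within both batches.

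The 38 genes of the extracellular matrix and fibrosis list, which share 5 members with the fibroblast list, were higher in 35 cases, with a median of 0.55. Col1a1, the main chain of type I collagen, stood at 90.5 ± 27.9 CPM (SD, n = 3) against 49.7 ± 6.58 CPM (SD, n = 4), a log2 fold change of 0.87 with an SE of 0.24. None of the members passed when adjusted over all genes and 5 passed when adjusted over the list alone. Camera gave an adjusted p of 4.76e-11, and the adjusted p was 0.631 with an estimated correlation. The list mean differed by 0.69 below a code number of 80 and by 1.14 at 80 and above, beside 0.77 over all (exact permutation p = 0.0857). Without G3 3 the median was 0.33.

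Marker lists of 6 other groups of cells were also called higher in the libraries labelled G3 PGC1aOE, and none was called lower. All 11 Schwann cell and neuronal markers were higher, with a median of 1.21 (0.72 without G3 PGC1aOE 1), including S100b at 2.29 ± 0.25 CPM (SD, n = 3) against 0.82 ± 0.37 CPM (SD, n = 4). This list had an adjusted p of 1.61e-07 in camera, and the adjusted p was 0.145 with an estimated correlation; 4 members passed when adjusted over the list alone and 0 over all genes. Its mean differed by 0.87 below a code number of 80 and by 0.83 at 80 and above (exact permutation p over all = 0.0286). That mean did not overlap between the groups either, which fixes its sign within both batches. Adipocyte markers were higher in 9 of 11 cases (median 0.76, adjusted p = 0.0014), and the adjusted p was 0.59 with an estimated correlation. Car3, an abundant carbonic anhydrase of fat, had a log2 fold change of 2.87 with an SE of 0.97, and the lipid droplet gene Plin1 one of 2.09 with an SE of 0.87. Without G3 PGC1aOE 3 Plin1 had 0.74 and Car3 1.97, Plin1 differed in log2 CPM by −0.19 below a code number of 80, and without G3 2 Car3 had 4.40. The adipocyte list mean differed by 0.19 below a code number of 80 and by 2.14 at 80 and above (exact permutation p over all = 0.114). Its median was 1.67 without G3 2 and 1.16 without G3 PGC1aOE 1.

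Endothelial markers were higher in 15 of 16 cases (median 0.51, adjusted p = 0.00143, and adjusted p = 0.59 with an estimated correlation), with log2 fold changes of 0.65 for Emcn and 0.68 for Eng, both surface glycoproteins of endothelium. Eng had 0.21 without G3 PGC1aOE 2, and below a code number of 80 the log2 CPM of Emcn and Eng differed by −0.093 and −0.15. Macrophage and monocyte markers were higher in 13 of 16 (median 0.29, adjusted p = 0.00257, and adjusted p = 0.59 with an estimated correlation), among them the chemokine receptor gene Ccr2 at 6.34 ± 2.40 against 2.41 ± 0.76 CPM and the Fc receptor gene Fcgr1 with a log2 fold change of 0.83. T, NK and B cell markers were higher in 4 of 5 tested (median 1.05, adjusted p = 0.0144, and adjusted p = 0.59 with an estimated correlation). Their expression was low, with a mean of −0.11 log2 CPM in G3 and 0.92 in the libraries labelled G3 PGC1aOE. Ptprc, a general leukocyte gene, had 0.51 and Cd3g had 1.30. Cd3g differed in log2 CPM by 1.26 below a code number of 80 and by −0.00086 at 80 and above. Epicardial and mesothelial markers were higher in 6 of 6 tested (median 0.80, adjusted p = 0.0255, and adjusted p = 0.59 with an estimated correlation), with Aldh1a2 at 1.19 (1.87 without G3 4) and Upk3b at 1.85. Without G3 PGC1aOE 3 Upk3b had 0.39 and without G3 4 it had 2.79, and its log2 CPM differed by −1.74 below a code number of 80. The exact permutation p of the list mean was 0.257, 0.4, 0.286 and 0.314 for these 4 lists, and 0 members of them or of the adipocyte list passed by either adjustment.

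Single libraries decided several of these calls. Without G3 PGC1aOE 2 the endothelial median was 0.099 (adjusted p = 0.487) and the T, NK and B cell median 0.54 (0.0834). Without G3 4 the macrophage median was 0.11 (adjusted p = 0.362), and without G3 PGC1aOE 1 it was 0.27 (0.109). It was 0.44 without G3 1, 0.55 without G3 2 and 0.12 without G3 3. The T, NK and B cell list was also lost without G3 1 (median 0.67, adjusted p = 0.116), without G3 PGC1aOE 3 (0.81, adjusted p = 0.118) and with DESeq2 (1.12, adjusted p = 0.101), and without G3 4 it had too few tested members. The epicardial list was lost without G3 2 (median 0.73, adjusted p = 0.0971), G3 3 (0.56, adjusted p = 0.0992) or G3 PGC1aOE 3 (0.17, adjusted p = 0.519). Without G3 PGC1aOE 1 the endothelial median was 0.79 and the epicardial one 1.37, and without G3 4 the latter was 1.23. Without G3 3 the T, NK and B cell median was 0.65. Within batches the endothelial mean differed by −0.075 below a code number of 80 and by 0.46 at 80 and above, the macrophage mean by 0.30 and 0.92, the T, NK and B cell mean by 0.24 and 0.085, and the epicardial mean by 0.056 and 0.36. With the code number as a covariate the median was 0.21 for the endothelial list (adjusted p = 0.16), 0.45 for the T, NK and B cell list (0.252) and 0.27 for the epicardial list (0.472).

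The other 8 marker lists did not pass. Their medians were 0.33 for atrial cardiomyocytes (adjusted p = 0.817), −0.05 for the conduction system (0.812), 0.26 for smooth muscle and pericytes (0.718), 0.22 for granulocytes and mast cells (0.718), 0.03 for skeletal muscle (0.718), 0.08 for endocardium and lymphatics (0.719), 0.22 for histone and nuclear RNAs (0.696) and −0.12 for erythroid cells (0.966). The erythroid list passed without G3 3, with a median of 0.74 (adjusted p = 0.0364). The granulocyte median was positive while its camera direction was down, and the erythroid median was negative while its direction was up.

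Lists of fuel oxidation genes were called lower in the libraries labelled G3 PGC1aOE. In the fatty acid uptake and oxidation list, 27 of 31 genes were lower, with a median of −0.33 (adjusted p = 7.65e-05, and adjusted p = 0.631 with an estimated correlation). The list mean was 7.38, 7.44, 8.15 and 8.08 log2 CPM in G3 1 to 4 and 7.42, 7.50 and 7.51 in G3 PGC1aOE 1 to 3, so the groups overlapped (exact permutation p = 0.4). The median was −0.16 without G3 3 and −0.21 without G3 4. Pdk4, the kinase that restrains pyruvate dehydrogenase, measured 202 ± 69.9 CPM (SD, n = 3) against 430 ± 185 CPM (SD, n = 4), a log2 fold change of −1.09 with an SE of 0.39. The oxidation enzyme gene Acadvl had −0.67. All 20 genes of branched-chain amino acid and ketone catabolism were lower (median −0.34, adjusted p = 5.61e-05, and adjusted p = 0.631 with an estimated correlation), among them Pcca at −0.45, Acadsb at −0.48 and Bckdhb at −0.40. In the TCA cycle list, 15 of 19 were lower (median −0.22, adjusted p = 0.00326, and adjusted p = 0.631 with an estimated correlation), led by Pcx, with Ogdh at −0.44 and Dlat at −0.41. Without G3 PGC1aOE 2 Acadvl had −0.36, Acadsb −0.30 and Dlat −0.20, and without G3 PGC1aOE 1 Acadsb had −0.73. The exact permutation p of the list mean was 0.143 for amino acid and ketone catabolism and 0.229 for the TCA cycle, and 0 members of the 3 lists passed by either adjustment.

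The list of regulators that work with PGC1alpha was called lower as well. Of 25 coactivators and partner regulators, 21 were lower, with a median of −0.36 (adjusted p = 1.52e-05, and adjusted p = 0.631 with an estimated correlation). Yy1, a transcription factor that binds the coactivator, had a log2 fold change of −0.50 with an SE of 0.19. The related coactivator gene Ppargc1b, at 12.9 ± 5.81 CPM (SD, n = 3) against 25.4 ± 11.8 CPM (SD, n = 4), had −0.98 with an SE of 0.41. Ppara, the nuclear receptor of fatty acid catabolism, had −1.17 with an SE of 0.52. Of 17 genes of mitochondrial dynamics and mitophagy, 13 were lower (median −0.19, adjusted p = 0.0106, and adjusted p = 0.631 with an estimated correlation), including the autophagy kinase gene Ulk1 at −0.53, Bnip3 at −0.72 and the fusion gene Mfn2 at −0.49. In insulin and IGF signalling, 20 of 23 were lower (median −0.37, adjusted p = 7.45e-05, and adjusted p = 0.631 with an estimated correlation), including Pik3r1 at −0.84, Igf1r at −0.89 and Akt1 at −0.46. Igf2, the only member of that list to pass when adjusted over the list alone, lay on the opposite side at 1.59. Ppara had −0.70 and Igf1r −0.52 without G3 PGC1aOE 2, without G3 4 Ppargc1b had −0.62, and without G3 1 Bnip3 had −0.38. Without G3 PGC1aOE 1 Bnip3, Mfn2 and Pik3r1 had −1.10, −0.81 and −1.38. No other member of the 3 lists passed by either adjustment, and the exact permutation p of their means was 0.114, 0.143 and 0.229.

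The fatty acid list mean differed by −0.24 below a code number of 80 and by −0.57 at 80 and above, beside −0.28 over all. For amino acid and ketone catabolism the values were −0.26 and −0.38, for the TCA cycle −0.17 and −0.37, for PGC1 partners −0.039 and −0.58, for mitochondrial dynamics −0.057 and −0.22, and for insulin signalling 0.078 and −0.44. The TCA cycle call was lost without G3 4 (median −0.19, adjusted p = 0.0568), without G3 PGC1aOE 1 (median −0.26, adjusted p = 0.0985) and with limma voom (median −0.072, adjusted p = 0.138), and the mitochondrial dynamics call was lost with the code number as a covariate (median −0.10, adjusted p = 0.0773). The insulin signalling call was lost with that covariate and the length trend removed together (median −0.23, adjusted p = 0.0512). The TCA cycle median was −0.10 without G3 3, −0.12 without G3 PGC1aOE 2 and −0.34 without G3 PGC1aOE 3. Without G3 PGC1aOE 1 the medians were −0.54 for PGC1 partners, −0.33 for mitochondrial dynamics and −0.77 for insulin signalling. Without G3 PGC1aOE 2 that of amino acid and ketone catabolism was −0.20, and without G3 PGC1aOE 3 that of insulin signalling was −0.24.

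Calcium handling and ion channel genes of the cardiomyocyte were lower in 24 of 29 cases, with a median of −0.33 (adjusted p = 1.23e-05, and adjusted p = 0.631 with an estimated correlation). Atp2a2, the calcium pump of the sarcoplasmic reticulum, measured 6259 ± 1865 CPM (SD, n = 3) against 11177 ± 2074 CPM (SD, n = 4), a log2 fold change of −0.84 with an SE of 0.33. The L-type calcium channel gene Cacna1c had −0.75 with an SE of 0.30 and the calcium release channel gene Ryr2 −0.95 with an SE of 0.40, and without G3 PGC1aOE 1 they had −1.16 and −1.55. No member passed by either adjustment. The list mean differed by −0.29 below a code number of 80 and by −0.31 at 80 and above, and the exact permutation p of that mean was 0.0286. This mean did not overlap between the groups, which by itself fixes its sign within both batches. Of 20 adult sarcomere genes, 12 were lower, and the list did not pass (median −0.21, adjusted p = 0.235). Myl2 at 0.73 and Tnni3 at 0.60 lay on the other side, and without G3 PGC1aOE 2 they had 0.24 and 0.097 while the list passed as lower (median −0.12, adjusted p = 0.047).

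Respiratory chain and mitochondrial ribosome genes were higher as lists in the libraries labelled G3 PGC1aOE, the nuclear-encoded lists through G3 PGC1aOE 2 and 3. For mitochondrially encoded mRNAs only G3 PGC1aOE 3, at a mean of 14.61 log2 CPM, lay above all libraries labelled G3. G3 PGC1aOE 2, at 13.96, lay below G3 3 and G3 4, at 14.00 and 14.13. Of 37 Complex I subunits, 34 were higher (median 0.55, adjusted p = 1.23e-05, and adjusted p = 0.692 with an estimated correlation), among them Ndufb2 at 184 ± 83.2 CPM (SD, n = 3) against 111 ± 13.8 CPM (SD, n = 4), Ndufv3 with a log2 fold change of 0.86 and Ndufa1 with 0.77. Complex II to IV subunits were higher in 23 of 26 cases (median 0.55, adjusted p = 0.00113, and adjusted p = 0.692 with an estimated correlation), with Cox7a2 at 0.63, Cox8b at 0.83 and Cox6c at 0.68. ATP synthase subunits were higher in 15 of 17 (median 0.49, adjusted p = 0.00916, and adjusted p = 0.692 with an estimated correlation), with Atp5mpl at 0.75, Atp5j2 at 0.94 and Usmg5 at 0.82. Mitochondrially encoded mRNAs were higher in 12 of 13 (median 0.29, adjusted p = 0.0124, and adjusted p = 0.692 with an estimated correlation), with mt-Nd3 at 0.78, mt-Co3 at 0.68 and mt-Atp6 at 0.56. Mitochondrial ribosomal proteins were higher in 69 of 75 (median 0.27, adjusted p = 5.61e-05, and adjusted p = 0.723 with an estimated correlation), with Mrpl20 at 0.65, Mrps16 at 0.70 and Mrpl52 at 0.73. The exact permutation p of the list mean was 0.371, 0.343, 0.343, 0.429 and 0.4 in that order, and 0 members passed by either adjustment.

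Below a code number of 80 all 5 of these list means were lower in the library labelled G3 PGC1aOE, by −0.31 for Complex I, −0.31 for Complex II to IV, −0.32 for ATP synthase, −0.0086 for mitochondrially encoded mRNAs and −0.24 for mitochondrial ribosomal proteins. Each of the 12 members named from the 4 nuclear-encoded lists was lower there as well. At 80 and above the list means were higher by 0.53, 0.47, 0.47, 0.16 and 0.31. Without G3 PGC1aOE 2 Ndufb2 had 0.43, Ndufv3 0.31, Ndufa1 0.36, Cox8b 0.45, Atp5j2 0.51, Mrps16 0.42 and Mrpl52 0.34, and without G3 PGC1aOE 3 Cox7a2 had 0.38, Usmg5 0.34, mt-Nd3 0.44 and mt-Co3 0.38. With each library's trend on gene length removed, the list medians were 0.11, 0.061, 0.044, 0.14 and 0.10, and none was called. With the code number as a covariate none was called either, at medians of 0.13, 0.075, 0.058, 0.093 and 0.0097. Without G3 PGC1aOE 2 the medians were 0.22 for Complex I (adjusted p = 0.325), 0.16 for Complex II to IV (0.248), 0.18 for ATP synthase (0.475) and 0.084 for mitochondrial ribosomal proteins (0.277). Without G3 PGC1aOE 3 they were 0.37 for Complex II to IV (adjusted p = 0.298), 0.38 for ATP synthase (0.344), 0.18 for mitochondrially encoded mRNAs (0.95) and 0.19 for mitochondrial ribosomal proteins (0.167). Without G3 1 the ATP synthase median was 0.43 (adjusted p = 0.0991) and that of mitochondrially encoded mRNAs 0.26 (0.102), and without G3 2 the latter was 0.13 (0.149). Without G3 PGC1aOE 1 the medians were 0.85 for Complex I, 0.86 for Complex II to IV, 0.82 for ATP synthase and 0.53 for mitochondrial ribosomal proteins.

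Cytosolic ribosomal proteins were higher in all 75 cases, with a median of 0.56 (adjusted p = 2.28e-14, and adjusted p = 0.631 with an estimated correlation). Rpl38, Rpl26 and Rps15a had log2 fold changes of 0.86, 0.88 and 0.74, and their log2 CPM differed by −0.011, −0.25 and −0.097 below a code number of 80. Without G3 PGC1aOE 3 Rps15a had 0.43. No member passed by either adjustment, and the exact permutation p of the list mean was 0.229. That mean differed by −0.19 below a code number of 80 and by 0.65 at 80 and above, and the median was 0.19 once the length trend was removed, still past the threshold. The median was 0.84 without G3 PGC1aOE 1 and 0.37 without G3 PGC1aOE 2.

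Interferon response genes were higher in 23 of 25 cases (median 0.43, adjusted p = 3.12e-05, and adjusted p = 0.631 with an estimated correlation). Mx1, an antiviral GTPase, had a log2 fold change of 1.20 with an SE of 0.50, the nucleic acid sensor gene Zbp1 0.96 with an SE of 0.43, and Ifit3 0.79 with an SE of 0.38 (0.40 without G3 PGC1aOE 2); Mx1 lay at only 1.16 ± 0.27 CPM (SD, n = 3) against 0.49 ± 0.24 CPM (SD, n = 4). The mean differed by 0.38 below a code number of 80 and by −0.017 at 80 and above, and with the code number as a covariate the median was 0.086 (adjusted p = 0.0548). The median was 0.74 without G3 4 and 0.17 without G3 PGC1aOE 2. Immediate early genes were higher in 20 of 23 cases (median 0.36, adjusted p = 0.00221, and adjusted p = 0.631 with an estimated correlation), with Egr2 at 1.23, Atf3 at 1.18 and Ier5 at 0.65. Without G3 PGC1aOE 1 Atf3 had 0.51, and its log2 CPM differed by 2.34 below a code number of 80 and by −0.25 at 80 and above. Their mean differed by 0.95 below a code number of 80 and by −0.36 at 80 and above. That call was lost without G3 1 (median 0.21, adjusted p = 0.0828) or G3 PGC1aOE 1 (median 0.065, adjusted p = 0.331) and with limma voom (median 0.16, adjusted p = 0.0874), and the median was 0.19 without G3 3.

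Senescence and secretory genes were higher in 11 of 18 tested cases (median 0.15, adjusted p = 0.0353, and adjusted p = 0.631 with an estimated correlation). Mmp12, a macrophage elastase, had a log2 fold change of 1.27, Igfbp7 0.79 and the chemokine gene Ccl2 0.80. Igfbp7 had 0.36 without G3 PGC1aOE 2 and differed in log2 CPM by −0.046 below a code number of 80, and Ccl2 had 0.40 without G3 PGC1aOE 3. Their mean differed by 0.30 below a code number of 80 and by 0.52 at 80 and above. The call was lost without G3 3 (median 0.18, adjusted p = 0.0675), G3 4 (0.19, adjusted p = 0.151), G3 PGC1aOE 1 (0.099, adjusted p = 0.359) or G3 PGC1aOE 3 (0.17, adjusted p = 0.167). It was also lost with DESeq2 (median 0.15, adjusted p = 0.0858) and with no filter on low counts (0.13, adjusted p = 0.0807). Its median was 0.35 without G3 2 and 0.24 without G3 PGC1aOE 2. For the interferon, immediate early and senescence lists the exact permutation p of the mean was 0.229, 0.343 and 0.114, and 0 members passed by either adjustment.

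The telomere, p53, DNA damage, fetal stress and cell cycle lists did not pass. Telomere and telomerase genes had a median of 0.00 (adjusted p = 0.586), with Pot1b, a component of the telomere cap, at a log2 fold change of 0.73 and Nop10 at 0.55. The median was 0.11 for p53 targets (adjusted p = 0.875), where Phlda3 and Rps27l had 1.01 and 0.96, and −0.12 for DNA damage response and repair (adjusted p = 0.11), where Chek2 and Mre11a had 1.17 and −0.45. Fetal and hypertrophic stress genes had a median of −0.01 (adjusted p = 0.715), with Acta2 at 1.10 and Actn1 at 0.46, and without G3 1 that median was 0.48 (adjusted p = 0.0296). Cell cycle genes had a median of 0.26 (adjusted p = 0.115), with Mki67 at 0.99 and Cdc20 at 1.13, and without G3 PGC1aOE 1 it was 0.55 (adjusted p = 0.00014), with no filter on low counts 0.37 (0.0341) and without mitochondrially encoded genes 0.34 (0.0376). Below a code number of 80 Phlda3, Rps27l and Nop10 differed in log2 CPM by −0.15, −0.11 and −0.30. Acta2, Actn1 and Cdc20 differed there by −1.63, −0.17 and −0.49. Pot1b, Chek2, Mre11a and Mki67 kept their sign, which for Pot1b and Mre11a was fixed by a lack of overlap between the groups.

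The stress and metabolic lists that remain did not pass either. ER chaperones of the unfolded protein response had a median of −0.17 (adjusted p = 0.111), with Herpud1 at −0.48 and Atf6 at −0.62; without G3 2, G3 3 or G3 4 the list passed, at adjusted p of 0.0278, 0.0363 and 0.0116, and it passed with DESeq2 (0.0175), with no filter on low counts (0.0441) and with the length trend removed (0.0425). ATF4 targets had a median of 0.12 (adjusted p = 0.398), with Nupr1 at 1.22 and Ddit3 at 0.81, and passed without G3 1 (adjusted p = 0.0362). Glycolysis and glucose uptake genes were split 11 to 12 (adjusted p = 0.326), with Gys1 at −0.59 and Hk2 at −0.46, and passed as lower without G3 PGC1aOE 2 (median −0.12, adjusted p = 0.0328) and with the length trend removed (median −0.17, adjusted p = 0.0407). Antioxidant genes had a median of 0.11 (adjusted p = 0.268), with Txnrd1 at −0.51 and Glrx at 0.41. Mitochondrial DNA maintenance had a median of −0.03 (adjusted p = 0.483), with Polg at −0.37 and Ssbp1 at 0.45. Mitochondrial chaperones, import and proteases were split 12 to 12 (adjusted p = 0.483), with Clpx at −0.65 and Timm9 at 0.61. The proteasome had a median of 0.12 (adjusted p = 0.483), with Psma5 at 0.48 and Psma3 at 0.45. Angiogenic factors had a median of 0.06 (adjusted p = 0.483), with Angpt2 at 0.86 and Aplnr at 1.87. The circadian clock had a median of 0.05 (adjusted p = 0.844), with Per3 at 0.83. Below a code number of 80 Psma5, Psma3, Ssbp1 and Timm9 differed in log2 CPM by −0.0098, −0.10, −0.20 and −0.12. Hk2 differed there by 0.046, and the other genes named with these lists kept their sign. For Nupr1, Txnrd1, Glrx, Polg and Clpx that sign was fixed by a lack of overlap between the groups.

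**Figure D2:**
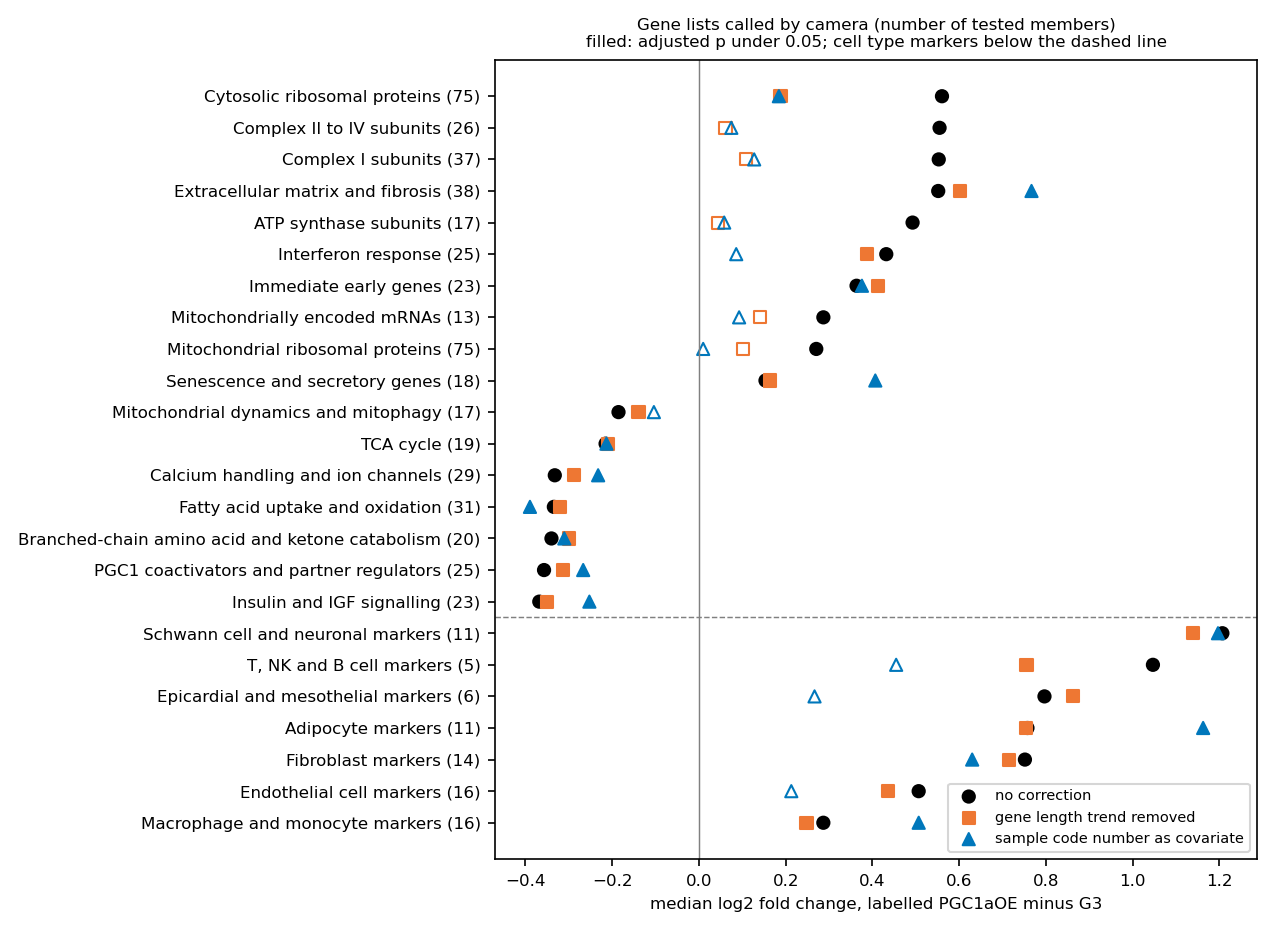
Median log2 fold change of each called gene list, libraries labelled G3 PGC1aOE minus G3 on the horizontal axis, without correction (black circles), with each library's gene length trend removed (orange squares) and with the sample code number as a covariate (blue triangles); filled symbols passed camera at an adjusted p under 0.05, and the number of tested genes stands in parentheses. Fibroblast markers kept medians of 0.75, 0.71 and 0.63, while Complex I went from 0.55 to 0.11 and 0.13.

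The largest spread between the libraries did not follow the labels. The first principal component, with 44.7% of the variance of the 500 most variable genes, put G3 4, G3 PGC1aOE 2 and G3 PGC1aOE 3 at 18.9, 25.4 and 19.1 and the other 4 libraries between −27.6 and −5.71, and these are the libraries with code numbers of 80 and above. The same libraries also had the highest total counts, from 14119403 to 16056740. The exact permutation p of the first component between the labelled groups was 0.4. The slope of log2 CPM, relative to the mean library, per doubling of gene length was 0.0997, 0.0263, 0.12 and 0.005 in G3 1 to 4 and 0.166, −0.249 and −0.168 in G3 PGC1aOE 1 to 3 (exact permutation p = 0.286). Mitochondrially encoded genes took 24.7%, 26.0%, 31.4% and 34.5% of counts in G3 1 to 4 and 27.7%, 32.4% and 42.4% in the libraries labelled G3 PGC1aOE (exact permutation p = 0.371). Correlations between libraries over tested genes ran from 0.901 to 0.979. The highest was across the labels, between G3 1 and G3 PGC1aOE 1. G3 PGC1aOE 1 correlated at 0.949 to 0.979 with the libraries labelled G3, and at 0.908 and 0.933 with G3 PGC1aOE 2 and 3.

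**Figure D3:**
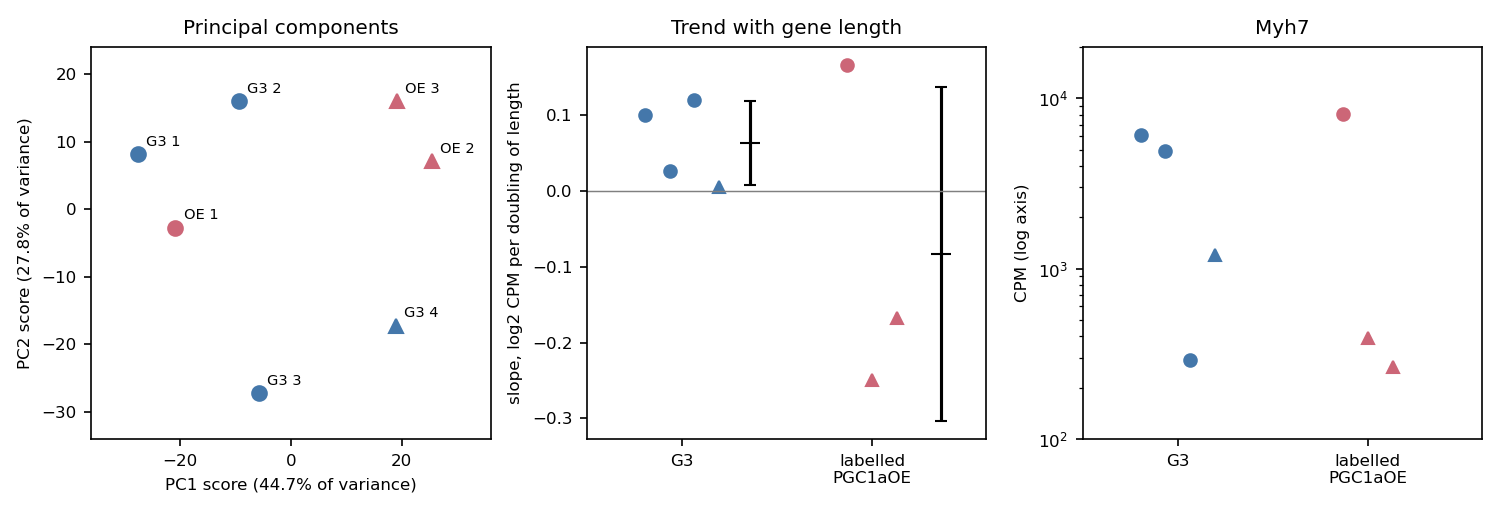
Left, scores of each library on the first 2 principal components; middle, slope of log2 CPM per doubling of gene length with the mean and SD of each group (n = 4 and n = 3); right, Myh7 CPM on a log axis; blue is G3, red is labelled G3 PGC1aOE (OE in the left plot), circles have code numbers below 80 and triangles 80 or above. The 3 triangles lie at 18.9 or more on the first component, and the slopes of −0.249 and −0.168 belong to G3 PGC1aOE 2 and 3.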

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

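The tests of cardiomyocyte share, of exchanged libraries, of an uncounted transgene, of the matrix list across splits, and of the respiratory and lower lists taken as sets, as well as every correction for gene length, GC content or code number, were chosen after the results were seen. Libraries were flagged where 1 of the 4 G3 values stood far from the other 3, which chance does in about 1 of 20 such tests, and 8 of 155 tests did so.

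Counts of Y-linked genes reached 1802 in G3 1, against 117 in the next highest G3 library. Adipocyte markers averaged 3.85 log2 CPM in G3 2, with 2.27 in the next library. Calcium handling genes averaged 6.79 in G3 4, below 6.93 in the next. Timm9 was at 3.71 log2 CPM in G3 3 and 3.17 in the next highest. Cacna1c was at 7.78 in G3 1 and 8.02 in the next lowest. Ccr2 was at 0.52 in G3 1 and 1.55 in the next lowest. Aldh1a2 was at 2.82 in G3 4 and 1.26 in the next highest. S100b was at 0.61 in G3 1 and −0.28 in the next highest.

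Fibroblast markers were higher in the libraries labelled G3 PGC1aOE, and the median of 0.75 was 0.71 with the gene length trend removed and 0.63 with the code number as a covariate, past the threshold both times, which argues against either as the whole cause. Of 35 splits of the 7 libraries, 1, the real one, gave a list p as small (2.14e-08, the next 2.76e-07). That is the least that 35 splits can give. It argues against chance only for this list taken alone, and not for a list picked from the 47 tested. The means of the Schwann cell and calcium handling lists also reached the smallest exact permutation p, 0.0286. For the overlapping matrix list chance cannot be excluded, since 2 of 35 splits gave a p as small. It was 2.98e-12 in the real split and 6.33e-18 in the split that sets G3 2, G3 3 and G3 4 apart. A lower share of cardiomyocytes stays open as part of the fibroblast difference. The fibroblast mean minus the mean of endothelial, smooth muscle and macrophage lists differed by 0.31 between groups (exact permutation p = 0.2). With so few libraries this cannot tell the 2 readings apart. Calcium handling genes were called lower, but adult sarcomere genes did not pass (camera, adjusted p = 0.235). Below a code number of 80 the endothelial, smooth muscle and macrophage means differed by −0.075, −0.39 and 0.30. These values rest on 1 library labelled G3 PGC1aOE. A change in fibroblasts with genotype stays open as a hypothesis, and the label it would rest on is not borne out by Ppargc1a.

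Of the 17 called pathway lists, 12 stayed called in their direction without the gene length trend. Without the GC trend 17 did, and with the code number as a covariate 10 did. These calls used the preset correlation, and 0 pathway lists passed with an estimated one. Keeping all 17 argues against the GC trend as the whole cause of the preset calls. Length and batch cannot be told apart from genotype for the set as a whole. The slope of log2 CPM per 10 points of GC content was 0.44 in G3 PGC1aOE 2 and from −0.20 to 0.10 in the others. For the 5 respiratory chain, ATP synthase, mitochondrially encoded and mitochondrial ribosome lists, 0 stayed called without the length trend and 0 with the code number, so either the gene length trend or the batch along the code number may account for them. For the 7 lower lists, 7 stayed called without the length trend at the preset correlation, with medians from −0.35 to −0.14, which argues against length as the whole cause, though none passed with an estimated correlation (adjusted p = 0.631), while 6 stayed called with the code number, but PGC1 partners and insulin signalling differed by −0.039 and 0.078 below a code number of 80 against −0.58 and −0.44 above, so batch stays open. Chance cannot be excluded for the counts of lists: 7 of 35 splits called at least as many pathway lists (17 in the real split, at most 21 in another) and 6 of 35 as many marker lists (7, at most 9). With 0 genes called in the real split, all 35 splits necessarily called at least as many, so this count tests nothing. The split of code numbers of 80 and above from the rest called the most, 191. The next 2 splits, G3 1 and G3 PGC1aOE 1 with G3 2 or with G3 3 against the rest, called 96 and 72. The cut at 80 was chosen after the data were seen and picks the libraries that stand apart on the first principal component. The 191 genes are therefore no separate evidence for that number as the axis. The same libraries also had the highest total counts, so code number and depth cannot be told apart.

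Ppargc1a was not higher in the libraries labelled G3 PGC1aOE, with −0.33 after removal of the length trend and −0.25 with the code number as a covariate, both more than 2 SE below 0.5. None of the 12 exchanges of 1 library between the groups, 0 in all, put every library then labelled G3 PGC1aOE above the rest, but this tells against a single swap only if RNA of the transgene is counted under the gene, so a swap stays open. Transgene RNA that was not counted under the gene could leave the total low. The test used the fatty acid list alone, with a median of −0.33 and an adjusted p of 0.631 with an estimated correlation. Other lists of mitochondrial and fuel oxidation genes pointed both ways. The TCA cycle median was −0.22, but those of Complex I, Complex II to IV and ATP synthase were 0.55, 0.55 and 0.49. These higher lists were not called without the length trend or with the code number, so an uncounted transgene stays open. An overexpression that had faded, or several wrong labels, was not tested, though the letters PC stand in the codes of these 3 libraries and of no other.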

How the results depend on the processing

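Alternatives on gene length, GC content and the code number were chosen after seeing the data. No gene passed under any setting except DESeq2, with 3, and the replicate block, with 4 (Retnla, H2-Ab1, Scd4 and H2-Eb1, chosen after their values were seen). Same-numbered libraries correlated at 0.456, 0.123 and −0.086 in their deviations from group means, and other pairs at −0.323 to 0.164. So few pairs cannot tell whether a number marks a shared litter or batch, and the labels do not say. The block was used only as an alternative. Ppargc1a stayed below 0 in all settings, from −0.81 to −0.15 when each library was left out, and passed in none.

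Leaving out each library gave 0 genes throughout, 12 to 17 pathway lists and 5 to 7 marker lists. These totals include lists not called in the main fit. Of its 17 and 7, 12 to 16 pathway lists and 5 to 6 marker lists were kept. The 17 pathway and 7 marker lists became 0 and 1 with an estimated correlation, 0 and 1 with fry, 10 and 4 with the code number as a covariate, and 11 and 4 with the length trend removed as well, of which 10 and 4 were among the 17 and 7 and the list of mitochondrial chaperones, import and proteases, then called lower, was not. The cause was not tested. Of the 17 and 7, DESeq2 kept 16 and 6, limma voom 15 and 7 (without the TCA cycle and immediate early lists), the block 15 and 5 (without the TCA cycle, senescence and macrophage lists, with the T, NK and B cell list too small to test, and with ER chaperones called lower in addition), the Y-linked covariate, which sets G3 1 apart much as leaving it out does, 14 and 6, and the fit with no filter on low counts 16 and 7. With the code number alone, Acta2 turned to −0.11 and the camera direction of the mitochondrial ribosomal list turned down, although its median was 0.0097. With the length trend removed too, Ndufa1 was −0.025, Acta2 −0.12, Myl2 −0.021 and Tnni3 −0.097, and the camera direction turned down for Complex I (although its median was 0.016), Complex II to IV (−0.064), ATP synthase (−0.023), mitochondrially encoded mRNAs (−0.043) and mitochondrial ribosomal proteins (−0.073). All other named genes and called lists kept their direction under all settings, while uncalled lists near 0 did not always. Of 102 genes that the naming rule selects, 54 moved by over 1.5 times in log2 fold change without 1 library, 26 of them without G3 PGC1aOE 2, 18 without G3 PGC1aOE 1 and 14 without G3 PGC1aOE 3. Only the FPKM fit with a pseudocount of 0.1 moved the median of all genes by over 0.1, to −0.11. In the simulation, 76.5% of 3-fold changes and 20.5% of 2-fold changes were recovered, so smaller differences in single genes were mostly not detectable even there. Its genes were drawn independently, with no trend along gene length or code number. The share recovered in the real libraries may therefore be lower. Ptn and Igf2, with log2 fold changes of 1.88 and 1.59, did not pass in the main test.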

Other observations

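Genes of the stressed ventricle varied widely between libraries of the same label and are named here after their values were seen. Myh7, the slow myosin heavy chain, measured 6071, 4906, 293 and 1206 CPM in G3 1 to 4 and 8072, 395 and 265 CPM in G3 PGC1aOE 1 to 3. Nppa, the atrial natriuretic peptide gene, measured 2400, 2477, 70.4 and 599 CPM in G3 and 3921, 448 and 1246 CPM in the others. Nppb, the related B-type peptide gene, measured 873, 207, 135 and 93.7 CPM and then 620, 144 and 167 CPM. Myh6, the fast myosin heavy chain, measured 15719, 8033, 21670 and 14024 CPM in G3 and 12294, 13594 and 7817 CPM in the others. Atrial cardiomyocyte markers averaged 5.71, 6.04, 2.88 and 3.05 log2 CPM in G3 1 to 4 and 3.51, 4.36 and 6.26 in G3 PGC1aOE 1 to 3.

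Ddx3y, a Y-linked gene, had 790 counts in G3 1 and between 0 and 4 in the other 6 libraries. It had 0 in every library labelled G3 PGC1aOE. The labels give no sex, but these counts set G3 1 apart, so sex may differ within G3 and between the groups. A covariate for Y-linked expression therefore acts much as leaving out G3 1 does, and the fetal and hypertrophic stress list had a median of 0.48 with that covariate (adjusted p = 0.0302) and 0.48 without G3 1 (adjusted p = 0.0296).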
